A study of Mus musculus with 4 samples.

How the data were processed

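The series holds 4 samples of total RNA from primary mouse hepatocytes, 2 given DMSO and 2 given the LXR agonist GW3965, each labelled with Cy3 and hybridised to its own array of Agilent design 028005. All 4 arrays sit on 1 slide and were read in 1 scan, with DMSO replicate a at position 1, GW3965 replicate a at 2, DMSO replicate b at 3 and GW3965 replicate b at 4. Per the file headers, the values are the signal intensity of each spot from Agilent Feature Extraction 10.7.3.1, on a linear scale, corrected for background and spatial trends and not scaled between arrays. The treatment label of the treated samples reads LXR against GW3965, taken here as the LXR agonist that the series description names. The submitters' processing notes name version 11.5.1.11 instead. The value table deposited by the authors holds the same processed intensity, with a largest difference of 0 over 62976 features of each array. Tools used before Feature Extraction are not given in the sources used here.

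Each array had 59305 spots other than controls, for 55681 probes, and 432 probes were printed more than once. The share of probes well above background, as the scanner software judged it, was 62.5% for DMSO replicate a, 65.2% for DMSO replicate b, 64.1% for GW3965 replicate a and 69.1% for GW3965 replicate b, and 0 spots were saturated. Spots marked as outliers numbered 135, 83, 141 and 88 in the same order and were left out. Processed signals were put on the log2 scale, spots of a probe were averaged, and each array's 75th percentile over probes other than controls was subtracted. After scaling, a bright spike-in control read 7.52, 7.47, 7.64 and 6.98 in that order, so that it was lowest on GW3965 replicate b. A probe was kept where it was well above background on both arrays of at least 1 group, which left 35479, and 9 probes were dropped for outlier spots. Gene names came from a table of RefSeq accessions for 26762 probes, and 28919 kept the name in the files. Where a name had several probes, the probe with the highest mean over the 4 arrays stood for it, giving 24637 genes and named features. Probe positions are on mm9 (NCBI37), as in the file headers.

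Genes were compared with limma 3.58.1 in R 4.3.3, with data.table (version 1.17.8) for reading, by a linear model of the group with moderated variance, no block and two-sided tests. The prior had 2.72 degrees of freedom beside 2 residual ones. P-values were adjusted by the Benjamini-Hochberg method over all genes, and also over each list alone, with a threshold of 0.05. Errors of log2 differences are the SE from this model. Where 1 group was well above background on 0 arrays, its signal was set no lower than the lowest level well above background, and the fold is given as a lower bound. The same was done for Epcam, Rnf186 and 4930412L05Rik, where 1 array of a group was not well above background. Figures were drawn with matplotlib 3.10.9.

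The 18 lists held 331 entries, of which 313 were measured. They cover LXR targets, fatty acid and triglyceride synthesis, cholesterol synthesis and uptake, bile acid synthesis and transport, fatty acid oxidation and PPARA targets, phospholipid remodelling and synthesis, gluconeogenesis, glycolysis and glucose uptake, inflammatory response, acute phase proteins, unfolded protein and integrated stress response, xenobiotic metabolism, cell cycle, and markers of hepatocytes, macrophages and leukocytes, endothelial cells, stellate cells and fibroblasts, and cholangiocytes. Of the 18 entries not measured, 4 had no probe under that name. Each list was tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists. Camera compares a list with all other genes, while fry tests the list by itself. At the preset correlation, the camera p draws on the spread across genes, with many degrees of freedom. With an estimated correlation it is read against the 2 residual ones.

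The groups, the test, the lists, the rule for named genes and the alternatives not marked as later were fixed before the data were examined. The rule names every measured LXR target, up to 4 members of each other list with the smallest p, and Abca1, Srebf1, Fasn, Scd1, Cyp7a1 and a few other lipid genes in any case, and some of the genes it names are not reported here. It also names up to 10 genes that passed in each direction or, if none passed, the 5 with the smallest p in each direction, leaving out clones, predicted models and probe names.

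The alternatives were quantile normalization, centring on the median, normexp background correction with an offset of 50, the deposited value table, no filter, a filter on all arrays, the mean of a gene's probes, each probe on its own, an intensity trend or a robust prior in limma, an adjusted p under 0.1, a fold of at least 1.5, the replicate letter as a block, each array left out in turn, camera with an estimated correlation, and fry. Combinations of the block with the filter on all arrays or with an estimated correlation, and the lists without shared members, were chosen after seeing the data. A block for the slide did not apply with 1 slide.

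The same steps were tested on simulated data with the measured spread, where 98% of genes changed by 3 on the log2 scale and 4% of those changed by 1 were called, with 11 unchanged genes called. Where arrays with the same letter also shared the deviations measured here, the same fit called 62% and 0% of these genes and 0 unchanged ones, with 0.11% of unchanged genes at an unadjusted p under 0.05, while a fit with the letter as a block called 100% and 100% and 82 unchanged ones. A simulated list of 20 genes shifted by 1 gave a camera p of 5.63e-29, and 2 of 50 random lists without a shift had a p under 0.05. These simulated genes varied independently of each other. The simulation therefore does not test camera on lists of correlated genes, such as cell cycle, with an estimated correlation of 0.98. The spread of each simulated gene was the moderated one from limma, which differs less between genes than the measured one. The shares called may therefore not carry over to the measured data, where the block called 15 genes.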

Results

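Hepatocytes, the main metabolic cells of the liver, were isolated from mice of the strain labelled bl6 and cultured in medium with 10% fetal bovine serum. They were then kept overnight at 0.5% serum with 5 µM simvastatin, a statin that inhibits cholesterol synthesis, and with 100 µM mevalonic acid, an early intermediate of that pathway. Along with these, the cells were given either DMSO or 1 µM GW3965, a synthetic agonist of the liver X receptors (LXR), nuclear receptors for oxysterols that control genes of cholesterol and fatty acid metabolism. The scanner's names for the treated arrays abbreviate the treatment as GL where their titles say GW, and the labels do not explain this, so GW3965 stands for the treatment as the labels give it. RNA levels were measured on 1-colour Agilent arrays, 2 per group, called replicates a and b of each group. Of 55681 probes, 34775 were well above background on DMSO replicate a, 36303 on DMSO replicate b, 35701 on GW3965 replicate a and 38481 on GW3965 replicate b. Values are log2 signal relative to the 75th percentile of each array. Across genes, which are not independent replicates, the SD of the difference between replicates was 0.56 on this scale in either group. The labels do not say whether the replicates are separate animals or cultures. The limma p-values for genes therefore measure only the spread between these samples, and the number of samples limits the precision. The camera p-values for gene lists at the preset correlation draw on the spread across genes, and do not measure how a list varies between samples.

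The comparison of GW3965 with DMSO asks which transcripts differ in hepatocytes given the LXR agonist. Abca1, the transporter that loads cholesterol onto lipid-poor apolipoprotein, was 5.96-fold higher with GW3965, a log2 difference of 2.58 ± 0.39 (SE, 2 arrays per group). Abcg1, another sterol transporter, was 3.94-fold higher, a log2 difference of 1.98 ± 0.29. Srebf1, which encodes a transcription factor of fatty acid synthesis genes, was 2.37-fold higher, by 1.24 ± 0.20, and Lpcat3, an enzyme that puts polyunsaturated fatty acids into phospholipids, was 2.07-fold higher, by 1.05 ± 0.21. Of the 24 genes of fatty acid and triglyceride synthesis, Srebf1 among them, 23 had a higher mean with GW3965, while markers of the hepatocyte itself had a median log2 difference of -0.01.

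Of the 22 genes on the list of LXR targets, 20 were measured, of which 4 rose, 0 fell and 16 did not pass the test in limma when adjusted over the list alone. Those that rose were Abca1, Abcg1 and Srebf1, each with an adjusted p of 0.012, and Lpcat3, with an adjusted p of 0.022. When adjusted over all 24637 genes, 0 of the 20 passed, and 8 had an unadjusted p under 0.05. Abca1 stood at 1.01 ± 0.64 (SD, n = 2) with DMSO and 3.58 ± 0.38 (SD, n = 2) with GW3965, and Abcg1 at 1.18 ± 0.33 and 3.16 ± 0.38. For Srebf1 the values were -0.84 ± 0.17 and 0.40 ± 0.04, and for Lpcat3 they were 3.35 ± 0.09 and 4.40 ± 0.20. On the mm9 build, the Abca1 probe lies on chromosome 4 from 53043944 to 53044003, the Abcg1 probe on chromosome 17 from 31252580 to 31252639, the Srebf1 probe on chromosome 11 from 60012664 to 60012723, and the Lpcat3 probe on chromosome 6 from 124653374 to 124653542. Among the members that did not pass, the log2 difference was 1.54 ± 0.54 (SE) for Scd2 and 0.82 ± 0.21 for Scd1, both stearoyl-CoA desaturases, 1.06 ± 0.49 for the fatty acid synthase Fasn, 0.99 ± 0.29 for the ubiquitin ligase gene Mylip and 0.79 ± 0.23 for Rnf145. Scd2 ran from 0.92 without GW3965 replicate b to 2.16 without GW3965 replicate a, and Fasn from 0.52 without DMSO replicate a to 1.595 without DMSO replicate b. These ranges follow the gap between replicates a and b, which ran the same way in both groups. In that order, Scd2 stood at 2.02 and 2.96 with DMSO and 3.41 and 4.65 with GW3965. Fasn stood at -1.37 and -0.29 with DMSO and -0.23 and 0.69 with GW3965. Smaller differences were found for the lipoprotein lipase Lpl (0.44 ± 0.35), Arl4c (0.26 ± 0.25) and Pltp (0.19 ± 0.28). The apolipoprotein genes Apoe (-0.01 ± 0.30), Apoc1 (-0.04 ± 0.30) and Apoc2 (0.01 ± 0.33), the sterol transporter Abcg5 (-0.16 ± 0.43), Smpdl3a (-0.17 ± 0.18) and Mlxipl (-0.21 ± 0.18) were near or below 0, and Nr1h3, which encodes LXR alpha, differed by 0.0007 ± 0.47. In 9 members both GW3965 arrays lay above both DMSO arrays, in 2 (Smpdl3a and Mlxipl) below them, and in 9 they overlapped, where chance would leave 33.33% of genes without overlap if arrays varied independently. Abcg8 and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, were not measured, since neither was well above background on both arrays of a group.

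As a group, the LXR targets were higher with GW3965, with a median log2 difference of 0.35 and a mean of 0.62 (camera, adjusted p = 3.98e-13 over 18 lists). This call was lost when camera estimated the correlation between genes (adjusted p = 0.157). The estimate was 0.011, near the preset 0.01, so the size of the correlation does not account for the loss. With an estimated correlation camera uses the 2 residual degrees of freedom, not the number of genes. At nearly equal correlations, the camera p before adjustment thereby rose from 4.43e-14 to 0.0175. Fry, which tests the list by itself, gave an adjusted p of 0.994 for a shared direction and 0.182 for either direction. The median was 0.060 without DMSO replicate b, 0.15 without GW3965 replicate a, 0.52 without DMSO replicate a and 0.55 without GW3965 replicate b, and the number of members that rose when adjusted over the list alone was 3, 6, 2 and 0 in that order. Without Srebf1, Scd1, Scd2 and Fasn, which the list shares with fatty acid synthesis, the median of the other 16 members was 0.11 (adjusted p = 2.81e-06), a test chosen after seeing the data. This call too was lost with an estimated correlation (p = 0.110 before adjustment).

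**Figure D1:**
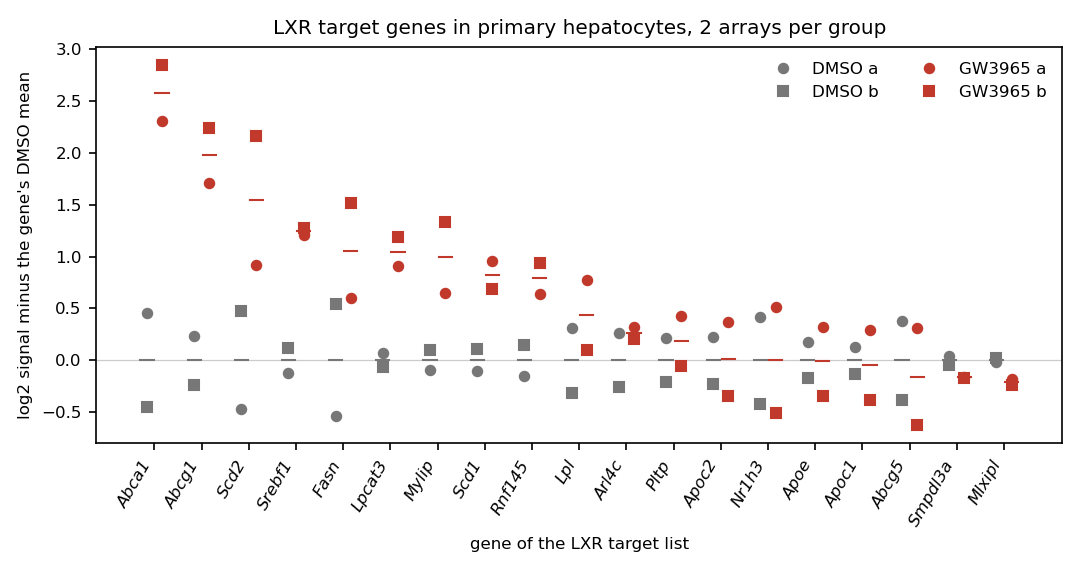
Log2 signal of the LXR targets reported here (horizontal axis) minus the mean of its DMSO arrays (vertical axis), with DMSO in grey and GW3965 in red, circles for replicate a, squares for replicate b and bars for the mean of 2 arrays. Abca1 and Abcg1 show the largest mean differences, 2.58 and 1.98, while Apoe and Nr1h3 show means near 0.

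All 24 genes on the list of fatty acid and triglyceride synthesis were measured, and as a group they were higher with GW3965, with a median log2 difference of 0.43 (camera, adjusted p = 3.99e-18). When camera estimated the correlation between genes the call was lost (adjusted p = 0.157). The estimate was -0.023, below the preset 0.01, so correlation between these genes does not account for the loss. As for the LXR targets, the p was then read against 2 residual degrees of freedom. The list had 1 member that rose when adjusted over the list alone, Srebf1 (limma, adjusted p = 0.0434), 0 that fell and 23 that did not pass, with 6 at an unadjusted p under 0.05. When adjusted over all genes, 0 passed. The means of 23 members were higher, and in 11 of these both GW3965 arrays lay above both DMSO arrays. Beyond the genes given above, the log2 difference was 0.84 ± 0.23 (SE) for the acyl-CoA synthetase Acsl3 and 0.75 ± 0.24 for the desaturase Fads2. By fry, the adjusted p was 0.150 for movement in a shared direction and 0.0365 for changes in either direction. With the replicate letter as a block, a combination not among the alternatives fixed beforehand, fry for either direction gave an adjusted p of 0.137. Srebf1 no longer passed over this list without any of the arrays in turn, where 0 members passed each time, nor with dim probes kept, where 0 passed as well.

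All 25 genes of cholesterol synthesis and uptake were measured, and as a group they were slightly higher with GW3965, with a median log2 difference of 0.10 (camera, adjusted p = 0.0388). This call too was lost when camera estimated the correlation (adjusted p = 0.598), though the estimate was -0.024, below the preset 0.01. Here too the p was then read against 2 residual degrees of freedom. When adjusted over the list alone, 0 rose and 0 fell by limma, 25 did not pass, and 0 had an unadjusted p under 0.05. The means of 17 members were higher and those of 8 lower. Insig1, which holds SREBP proteins in the endoplasmic reticulum, differed by 0.54 ± 0.25 (SE). Dhcr7, which makes cholesterol from its last precursor in the Kandutsch-Russell pathway, differed by 0.38 ± 0.32, and the mevalonate pathway enzyme Mvd by 0.29 ± 0.23. With each array left out in turn, Insig1 ran from 0.27 to 0.82, Dhcr7 from 0.035 to 0.72 and Mvd from 0.099 to 0.49. The list's call ended with arrays centred on their median (0.046, adjusted p = 0.0593), with dim probes kept (0.10, adjusted p = 0.0606), without DMSO replicate b (0.11, adjusted p = 0.668) and without GW3965 replicate a (0.066, adjusted p = 0.643).

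The genes of the inflammatory response were slightly lower as a group, with a median log2 difference of -0.14 over 20 measured of 20 listed (camera, adjusted p = 0.0303). When camera estimated the correlation, at 0.45 for this list, the call was lost (adjusted p = 0.959). The means of 18 members were lower, while 0 rose and 0 fell by limma when adjusted over the list alone, and 0 had an unadjusted p under 0.05. The log2 difference was -0.69 ± 0.59 (SE) for the cytokine gene Il1b, -0.37 ± 0.35 for Tnf, -0.27 ± 0.19 for the adhesion molecule Vcam1 and -0.16 ± 0.27 for Tnfaip3. Il1b ran from -1.32 without GW3965 replicate a to -0.060 without GW3965 replicate b. On replicates a and b it stood at -0.42 and -1.59 with DMSO and at -1.07 and -2.33 with GW3965. With each array left out in turn, Vcam1 kept its sign (-0.36 to -0.18), while Tnf (-0.77 to 0.03) and Tnfaip3 (-0.43 to 0.12) changed sign. The direction turned without DMSO replicate a (0.20, adjusted p = 0.00815) and without GW3965 replicate b (0.075, adjusted p = 0.739), and the median was -0.58 without DMSO replicate b and -0.38 without GW3965 replicate a. The call also ended with quantile normalization (adjusted p = 0.0679), with arrays centred on their median (adjusted p = 0.113) and with dim probes kept (adjusted p = 0.272). It was stronger with the replicate letter as a block (camera, adjusted p = 0.000141). Fry with that block, not among the alternatives fixed beforehand, gave an adjusted p of 0.571 for a shared direction.

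None of the other 14 lists passed camera, and of their 224 measured members 0 passed limma when adjusted over the list alone, while 1, Lpcat3, had an unadjusted p under 0.05. Among metabolic lists, the median log2 difference was -0.08 for bile acid synthesis and transport (17 measured of 20, adjusted p = 0.275), with 0.31 ± 0.19 (SE) for the canalicular transporter Abcc2 and -0.31 ± 0.30 for Nr1h4, which encodes the bile acid receptor FXR. The list's probe for Baat was well above background on 1 of the 2 GW3965 arrays, with a log2 difference of -0.50 ± 0.39. Fatty acid oxidation and PPARA targets had a median of -0.04 (22 of 23, adjusted p = 0.816), with 0.27 ± 0.18 for Pdk4 and -0.22 ± 0.23 for the carnitine palmitoyltransferase Cpt1a. Phospholipid remodelling and synthesis had a median of 0.01 (17 of 19, adjusted p = 0.642), with 0.29 ± 0.32 for Lpcat1 and -0.39 ± 0.48 for Mboat1. Gluconeogenesis had a median of -0.09 (12 of 12, adjusted p = 0.816), with 0.38 ± 0.20 for Foxo1 and -0.31 ± 0.59 for Pck1, and glycolysis and glucose uptake had a median of 0.008 (17 of 17, adjusted p = 0.921), with 0.18 ± 0.18 for Pkm and 0.38 ± 0.43 for the phosphofructokinase gene Pfkl. Xenobiotic metabolism had a median of -0.03 (18 of 21, adjusted p = 0.816), with 0.30 ± 0.21 for Cyp1a2 and -0.24 ± 0.41 for Ugt2b5.

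The unfolded protein and integrated stress response had a median of 0.02 but a mean of -0.007 and a downward camera test (18 of 18, adjusted p = 0.816), with -0.11 ± 0.21 (SE) for the chaperone gene Hspa5 and 0.12 ± 0.18 for Calr. Acute phase proteins had a median of -0.02, a mean of 0.02 and a downward test (18 of 18, adjusted p = 0.921), with -0.12 ± 0.38 for Saa1 and 0.36 ± 0.76 for Crp. Cell cycle genes had a median of -0.14 (15 of 17, adjusted p = 0.275), with -0.19 ± 0.27 for Pcna and -0.27 ± 0.50 for Cdk1. Among cell type markers, the median was -0.01 for hepatocytes (18 of 20, adjusted p = 0.816), with -0.25 ± 0.71 for Hnf4a and -0.12 ± 0.26 for Rbp4. Markers of macrophages and leukocytes had a median of 0.02, a mean of -0.003 and a downward test (18 of 19, adjusted p = 0.816), with -0.30 ± 0.27 for Lyz2 and 0.71 ± 0.76 for Cd5l. Endothelial markers had a median of 0.11 (13 of 13, adjusted p = 0.606), with 0.25 ± 0.21 for Tek and 0.18 ± 0.37 for Pecam1, and stellate cell and fibroblast markers had 0.11 (13 of 14, adjusted p = 0.816), with 0.39 ± 0.18 for Pdgfrb and 0.21 ± 0.24 for Col3a1. Cholangiocyte markers had a median of 0.06 (8 of 9, adjusted p = 0.921), with 0.49 ± 0.22 for Krt23, -0.22 ± 0.30 for Sox9 and -0.49 for Epcam, which was well above background on 1 of the 2 GW3965 arrays, with the other set no lower than the lowest such level.

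With an array left out, lists that had not passed did so, in directions that depended on the array. Acute phase proteins had a median of 0.49 without DMSO replicate a and 0.50 without GW3965 replicate b, but -0.45 without DMSO replicate b and -0.51 without GW3965 replicate a. In the same order, the median was 0.40, 0.41, -0.34 and -0.39 for hepatocyte markers, 0.31, 0.25, -0.38 and -0.46 for macrophage and leukocyte markers, 0.24, 0.21, -0.25 and -0.32 for fatty acid oxidation and PPARA targets, and -0.58, -0.43, 0.39 and 0.29 for cell cycle genes, each with an adjusted p under 0.05. Without DMSO replicate b and without GW3965 replicate a, endothelial markers passed at 0.54 and 0.51, bile acid synthesis and transport at -0.20 and -0.21, and xenobiotic metabolism at -0.16 and -0.24, with 0.16 for the last without GW3965 replicate b. Gluconeogenesis passed without DMSO replicate b, at -0.42, and was -0.46 without GW3965 replicate a, which did not pass. Without DMSO replicate a and without GW3965 replicate b the median had the opposite sign and did not pass for endothelial markers (-0.20 and -0.22), bile acid synthesis and transport (0.036 and 0.084) and gluconeogenesis (0.27 and 0.29).

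**Figure D2:**
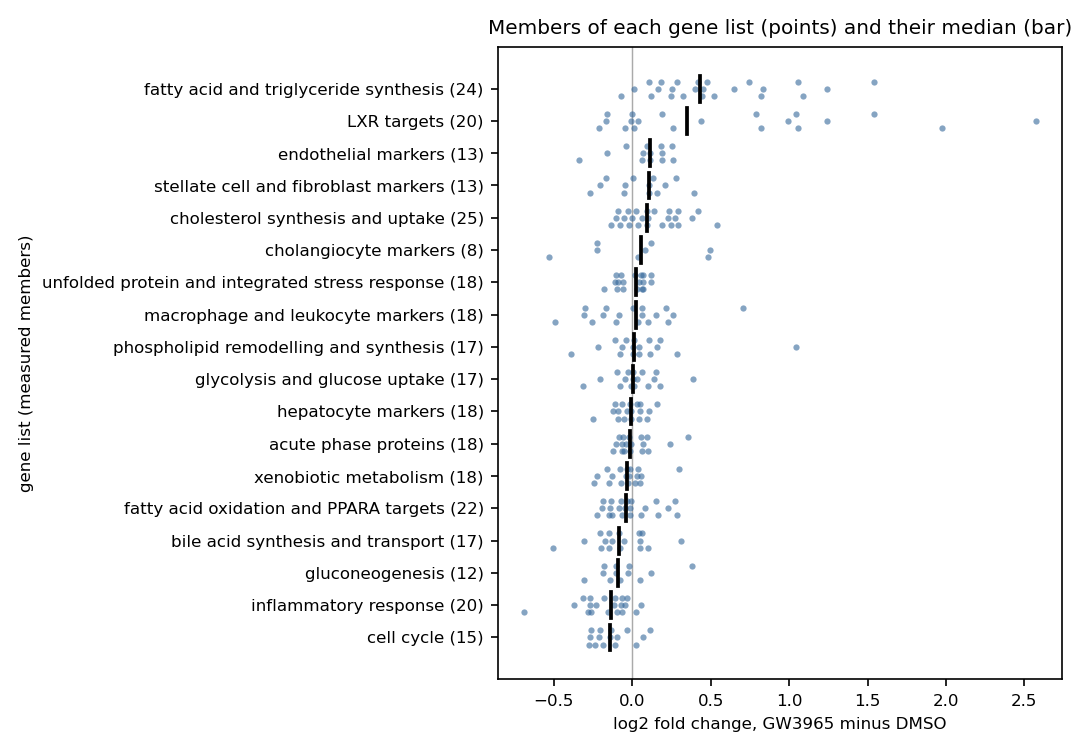
Log2 fold change, GW3965 minus DMSO (horizontal axis), of the measured members of each of the 18 gene lists (vertical axis, number measured in brackets), with a point for each gene and a bar for the list's median. Fatty acid and triglyceride synthesis (median 0.43) and LXR targets (0.35) lie to the right of the other lists, whose medians run from -0.14 to 0.11.

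Over all 24637 genes and named features, limma called 0 at an adjusted p under 0.05, and the smallest adjusted p was 0.940. At an unadjusted p under 0.05 there were 203, of which 159 were higher and 44 lower with GW3965, where chance would give 1232 if the arrays of a group varied independently. The exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333 and so cannot reach 0.05. Arrays of the groups did not overlap for 3932 genes, which is 16.0% against the 33.33% that chance gives for independent arrays. Without overlap, 79 genes were at least 2-fold higher and 35 at least 2-fold lower, of which 23 and 18 were well above background on all arrays. With clones, predicted models and probe names left out, the smallest unadjusted p-values among higher genes belonged to Nhlh2, Nptx2, Abcg1, Abca1 and Srebf1. Nhlh2, a transcription factor of neurons, was at least 1.76-fold higher and Nptx2, a neuronal pentraxin, at least 1.79-fold higher, both well above background on 0 DMSO arrays and 2 GW3965 arrays. The p-values of Nhlh2 and Nptx2 rest on DMSO means of -7.63 and -7.67. The lowest levels well above background were -5.70 on DMSO replicate a and -6.00 on DMSO replicate b. Among lower genes, with the same names left out, the smallest p-values belonged to Esco2, Mcpt8, Mmd2, Hus1b and Dnal1. Esco2, a cohesin acetyltransferase, differed by -0.80 ± 0.19 (SE), and Dnal1, a dynein light chain, by -0.63 ± 0.19. Mcpt8, a protease of basophils, was at least 2.17-fold lower, Mmd2 at least 3.04-fold lower and Hus1b at least 1.60-fold lower. Mcpt8, Mmd2 and Hus1b were well above background on 2 DMSO arrays and 0 GW3965 arrays. With normexp background correction, which shrinks dim signals, the log2 difference was 0.37 for Nhlh2, 0.35 for Nptx2, -0.25 for Esco2, -0.35 for Mcpt8, -0.34 for Mmd2, -0.16 for Hus1b and -0.20 for Dnal1. Without DMSO replicate b, 1 feature known only by its probe name passed and 416 had an unadjusted p under 0.05.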

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

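With all arrays kept and no replicate block, limma called 0 genes under each alternative, with 56 (normexp) to 536 (no filter) at an unadjusted p under 0.05. The replicate letter as a block called 15 genes, and the block with the filter on all arrays, chosen after seeing the data, called 12, of which 3 were shared. The 15 include 0 members of the LXR list, while the 12 include Scd2 (adjusted p = 0.00843), Abca1, Abcg1 and Srebf1 (adjusted p = 0.0218 each). The labels do not say that equal letters pair the samples, though the deviations of arrays with the same letter from their group means had a correlation of 0.72 across genes. In simulated data with such shared deviations, 0.11% of unchanged genes had an unadjusted p under 0.05 with no block, against 0.824% of the genes measured here. The simulated genes passed through no background filter, and the measured share was 0.399% with the filter on all arrays. In the same simulation the fit with the block called 82 unchanged genes, so calls with the block can include false ones. Over the LXR list alone, 10 members passed with the block and 10 with the block and that filter, and over the list of fatty acid and triglyceride synthesis 13 passed with either, all of them higher. Among genes named outside the rule, the block gave an adjusted p of 0.00667 for Rnf186, and the block with that filter gave 0.0218 for Gramd1b, 0.0264 for Scd3 and 0.0382 for Pnpla3. With an array left out, 0 to 1 genes and 0 to 6 LXR members passed, and the lone sample is then assumed to vary like the other group.

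Instead of 4 lists, 0 passed with an estimated correlation, 0 with fry for a shared direction, 1 with fry for either direction, 2 with median centring, 2 with no filter, 3 with quantile normalization, 5 with the block, 5 with the block and the filter on all arrays, 0 with the block and an estimated correlation (chosen after seeing the data) and 9 to 12 with an array left out. The block gained cell cycle (-0.14, adjusted p = 0.00593). Camera with the block and an estimated correlation leaves too few residual degrees of freedom to decide. Even fatty acid synthesis had an unadjusted p of 0.0997. LXR targets stayed at 0.35, cholesterol synthesis at 0.10 and fatty acid synthesis at 0.43 where only the test differed. None passed with an estimated correlation, with or without the block, or fry, except fatty acid synthesis with fry for either direction. Cholesterol synthesis also did not pass with median centring (0.046) or no filter (0.10), and ran from 0.066 to 0.13 with an array left out.

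Leaving out arrays in turn reversed medians, which ran from -0.51 to 0.50 for acute phase proteins, -0.58 to 0.39 for cell cycle, -0.32 to 0.24 for fatty acid oxidation, -0.39 to 0.41 for hepatocyte markers, -0.58 to 0.20 for inflammatory response, -0.46 to 0.31 for macrophage and leukocyte markers and -0.24 to 0.16 for xenobiotic metabolism. These reversals follow from the difference between replicates a and b, since leaving out an array shifts a gene's group difference by part of the gap between that group's replicates. Apart from the degrees of freedom of camera with an estimated correlation, the cause of the other changes was not tested. Of 94 named genes over up to 16 settings, 6 changed sign with all arrays kept and 45 with an array left out. Genes that the filter on all arrays removed, such as Nhlh2, had 14 settings. An adjusted p under 0.05 was reached by 6 named genes in a setting with the block and by 0 with an array left out. Of the 15 genes called with the block, 12 were not well above background on every array, where signal over background limits the size of a fold. A block for the slide was not run, as there is 1 slide.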

Other observations

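All tests of explanations given here were chosen after the results were seen, and the genes named here outside the lists were chosen after their values were seen. Beside the listed genes, the sterol transfer protein gene Gramd1b had a log2 difference of 1.27 ± 0.21 (SE, GW3965 minus DMSO) and the desaturase gene Scd3 one of 1.23 ± 0.25, with both GW3965 arrays above both DMSO arrays, though another Scd3 probe gave -0.04. Pnpla3, a lipid droplet protein on the list of fatty acid and triglyceride synthesis, differed by 1.09 ± 0.59, with overlapping arrays, and its other probe by 2.40. On replicates a and b, Pnpla3 stood at -3.43 and -4.66 with DMSO and at -2.35 and -3.56 with GW3965. Rnf186, a ubiquitin ligase gene, was at least 6.61-fold higher and was well above background on 1 of the 2 DMSO arrays. In limma with no block 0 of these genes passed over all genes, as each had an adjusted p of 1, and 3 of them (Gramd1b, Scd3 and Rnf186) had an unadjusted p under 0.05.

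Try4 and Cpa1, genes of pancreatic digestive enzymes, were lower on DMSO replicate a than on the other arrays. Try4 stood at -2.74 there, against 0.36 on DMSO replicate b, -0.01 on GW3965 replicate a and 0.16 on GW3965 replicate b, and Cpa1 at -3.50 against -0.98, -1.13 and -1.14. The chemokine genes Ccl3 and Ccl4 differed between groups by -0.70 ± 0.57 (SE) and -0.59 ± 0.53, with overlapping arrays.

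On replicate b of both groups, the acute phase list was lower than on replicate a in 18 of 18 members, with a median difference of -0.92 for DMSO and -1.05 for GW3965, and hepatocyte markers were lower by medians of -0.83 and -0.84. Endothelial markers were higher by 0.74 and 0.65 and cell cycle genes by 1.00 and 0.99. Scaling that depends on intensity is argued against, since the acute phase median was still -0.99 (mean of both groups) after quantile normalization. A smaller share of hepatocytes with all other cell types raised is argued against by macrophage and leukocyte markers, whose median was -0.73 (mean of both groups). Stellate cell and fibroblast markers, like endothelial ones, were higher, by 0.41 and 0.29. A change in which cell types moved in different directions is not covered by this test and stays open. Separate animals or cultures and the place on the slide, where replicates a took positions 1 and 2, stay open, and no difference in the study's design between the letters was tested because the labels name none.

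On chromosome 4, 4 probes on the strand of Abca1, the nearest of them 174 kb from the Abca1 probe (mm9), were brighter with GW3965. They were picked for a rise of more than 2-fold and for being well above background on both GW3965 arrays. Of these, 3 were at least 6.75-fold, 10.2-fold and 15-fold brighter, with 0 DMSO arrays well above background, and 4930412L05Rik was at least 9.92-fold brighter, with 1 of the 2 DMSO arrays well above background. A raised signal across the whole region is argued against, as the median log2 difference of 9 neighbouring genes within 1 Mb was -0.00022, though Mexis, on the same strand and the nearest of them to these probes, was at least 1.41-fold brighter, so that a rise over a shorter stretch stays open. Whether Abca1 RNA binds these probes stays open. Their mean bounded difference exceeded that of Abca1 by 0.76 ± 0.57 (SE), within 2 SE. As it rests on lower bounds, this value may understate the excess, so it does not favour such binding.

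On chromosomes 2 and 9, 7 probes for 5 predicted transcripts had log2 differences of -2.29 to -3.15. All 7 were also lower on replicate b than on replicate a of both groups. ENSMUST00000099046, for example, stood at 0.92 and -1.16 with DMSO and -2.86 and -3.67 with GW3965. A candidate explanation is that they read a single repeated sequence, since 7 of the 7 hold a stretch of 12 bases of another of them, while the highest number in 1000 random sets of 7 probes was 2. The random sets came from the whole array and were not matched for probes of the same transcript or region. More genomic DNA in the DMSO samples stays open: the median over 1494 olfactory and vomeronasal receptor probes was -0.20, but 235 of them were well above background on all arrays, so that it mostly reads background and decides nothing. Whether GW3965 lowers RNA from such a repeat was not tested.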
